A study of Mus musculus with 4 samples.

How the data were processed

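The series holds 4 biological replicates of 1 group, Sham, and no second group. Per the labels, each is heart tissue of C57BL/6J mice aged 12 weeks, taken 2 weeks after a sham operation from the place that would border an infarct. Total RNA was isolated with Trizol and poly(A)-selected, and long RNA libraries were sequenced as paired reads of 100 bases, per the labels' protocols. The free-text description of replicate 4 places it at the edge of an infarct without the word sham, while its title, source name and treatment call it sham. It was kept in the Sham group.

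The authors deposited 2 files. The first is a table of signal values, the read counts of 35299 loci divided by 1 size factor per library by the authors, named below normalised read counts. Its columns are headed 3RL, 7LR, 8R and 12RL. These names are in no label, so the libraries are known to be Sham and are not tied to replicate numbers. The second file holds exon positions of transcript models in 1-based coordinates on mm9, pooled over the series. Per the submitters' processing notes, the build was mm9 and the tools were TopHat2 2.0.5, Cufflinks 2.0.2, HTSeq 0.5.4p2 and DESeq. The strandedness of the libraries, the counting mode and the libraries that entered the assembly are not given in the sources used here. How reads of overlapping or antisense loci and of near-identical copies were counted is therefore not known, and levels of such loci may be wrong.

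The models carry UCSC identifiers and no gene symbols. Of 49347 UCSC identifiers, 0 were found in the reference tables used here, which describe a later build (GRCm38). Loci are therefore given by chromosome, start and end on mm9, with no gene name, and no coordinate was converted. The lists and pairs of gene symbols fixed before the data were examined were not used, and comparisons of coding with noncoding genes and of replicate 4 with the others were not made. The 5 highest loci of each ranking are named, fewer than the 15 or 10 per ranking that were set before the data were examined, because a position alone says little.

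Every value in each column was a whole multiple of 1 step within 0.001, in 100% of loci, so whole reads were recovered. The totals were 140554089 reads in 3RL, 142524825 in 7LR, 160670654 in 8R and 108345923 in 12RL. At a count of 10 reads, counting error alone gives a CV of 31.6%. The geometric mean of the 4 size factors was 0.800. The medians of the ratios to the geometric mean of the 4 libraries ran from 0.988 to 1.02. Size factors set by such medians on these 4 libraries alone would make each of them 1, so the values may be scaled over a wider set of libraries.

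Values were taken as log2(value + 1) for level, spread, agreement and the trend with length, so that differences of low loci are understated. Shares of counts and the CV used untransformed values. Values were not divided by locus length, so abundant below means high in read count. Loci with a mean of 10 or more entered the comparisons of spread and agreement, and loci with a mean of 50 or more entered the rankings of variability. Variability was ranked by the residual of log10 CV on a running median of 501 loci ordered by mean. A library was said to stand apart at a locus where Dixon's ratio of the untransformed values passed the 95% critical value for 4 values. Loci without a UCSC model were compared with loci that have one by the difference of medians within each library, among loci with a mean above 0, with an exact two-sided sign-flip test whose smallest p with 4 libraries is 0.125. Their SD was set against 10000 random sets of the other loci matched on 10 bins of the mean, drawn with replacement in the 2 bins where the other loci were too few. These comparisons took the place of coding against noncoding genes and were chosen after the files were seen. The deviation of each library from the mean of the 4 was compared with the longest spliced UCSC model of the locus by Spearman's rank correlation across loci, which are not independent replicates. Medians of transcript models were compared by permutation tests of 100000 resamples, and neighbourhoods by Fisher's exact test. Alternatives were other pseudocounts, minimum means, scaling to equal table totals, the median of ratios over the 4 libraries, TMM scaling of the recovered reads (edgeR 4.0.16 in R 4.3.3), edgeR's tagwise dispersion, a chi-square against Poisson and leaving out each library. The other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

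The steps were tested on simulated data made from the real means and size factors, with the edgeR common dispersion of 0.0217 for every locus. Simulated loci were independent, while real loci may differ in dispersion and share trends, so simulated rates are a rough guide. Of loci raised in 1 library, the ranking of variability placed 56.0% of those raised 2-fold and 100% of those raised 3-fold, 5-fold or 10-fold among the 200 most variable of 14424 loci. Without a trend, the largest rank correlation with length had a size of 0.0150. Of 100 random sets tested for spread, 4.00% had a p under 0.05.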

Results

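The series profiled poly(A)-selected long RNA of sham-operated adult mouse heart in 4 biological replicates of 1 group. The free-text description of replicate 4, unlike its other labels, names the edge of an infarct without calling it sham, and the table does not show which of the 4 libraries, 8R included, is that replicate. The libraries held between 108345923 (12RL) and 160670654 (8R) recovered reads, with a mean of 138023873 ± 21758661 (SD, n = 4). Of 35299 loci in the table, 23580 were above 0 in all 4 libraries, and 18912 had a mean normalised read count of 10 or more. Each library had between 25390 and 26039 loci above 0. Levels, spread between hearts and the transcript models are described, since there is no second group to compare.

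The loci with the most counts in the poly(A) RNA of these hearts were mitochondrial, while most counts were nuclear. Counts were not divided by locus length, so a share of counts is not a share of RNA molecules. Loci on the mitochondrial chromosome, which encodes subunits of the respiratory chain, took 30.7% ± 1.33 of all normalised counts (SD, n = 4), from 29.2% in 7LR to 32.3% in 8R. The single-exon mitochondrial locus at chrM 5327 to 6938 was the most abundant of all, with 11.4% ± 0.532 of the counts. It was followed by chrM 12406 to 15288 with 6.79% ± 0.433, chrM 9876 to 11542 with 4.05% ± 0.241 and chrM 7010 to 7699 with 3.33% ± 0.240. The most abundant nuclear locus, at chr14 55558018 to 55626715 with UCSC models of up to 41 exons, took 2.89% ± 0.298.

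The 15 most abundant loci together took 39.4% ± 1.05 of the counts, and 6 of them were mitochondrial. All 15 had a UCSC model. When mitochondrial loci were left out, the 15 highest nuclear loci took 16.5% ± 0.338 of the remaining counts. Nuclear loci among the first 15 were found at chr5 122903523 to 122952355 (1.52% ± 0.0707) and chr2 113873025 to 113878547 (0.811% ± 0.106). The locus with the most exons among them, 313 exons at chr2 76541034 to 76820604, took 0.531% ± 0.150. Its normalised read counts were 706034 in 3RL and 701734 in 8R, against 1092008 in 7LR and 1105123 in 12RL.

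The 4 hearts gave closely similar profiles. Pearson's r of log2 values across the 18912 loci ran from 0.986 (8R and 12RL) to 0.991 (7LR and 12RL) over the 6 pairs of libraries, and Spearman's rho from 0.987 to 0.992. The median SD of a locus over the 4 libraries was 0.19 on the log2 scale. No pair was a repeat of 1 library: the chi-square per degree of freedom of the recovered reads was at least 31.3 in every pair, where sampling noise alone gives about 1. Among 14424 loci with a mean of 50 or more, the median CV was 10.6%, and 199 loci had a CV above 50%.

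A small set of loci differed strongly between these hearts, and library 8R was most often the highest. The CV of untransformed values can rise further with 1 high value than with 1 low value. The ranking therefore favours loci high in 1 library, whichever library that is. Of the 15 most variable loci, 12 were highest in 8R, 2 in 7LR and 1 in 3RL, and 10 were lowest in 3RL. The locus at chr1 192992815 to 193007212 had 8258 normalised counts in 8R, against 395 in 3RL, 1195 in 7LR and 807 in 12RL. The locus at chr15 101084668 to 101105223 had 24356 in 8R and 6521 in 7LR, against 1135 in 3RL and 1116 in 12RL. At chr8 10984675 to 11008527 the count of 19723 in 8R was 4.31 times the next highest, and at chr4 48058015 to 48099485 the count of 12477 was 6.40 times the next highest. At chr17 31972741 to 31992737 both 8R (24409) and 7LR (13171) were above 3RL (3592) and 12RL (3242). The ranking rests in part on 8R: without it, 7 of the 15 loci remained among the 15 most variable. It also rests on the measure: 6 remained with the SD of log2, 8 with edgeR's tagwise dispersion and 0 with the chi-square against Poisson.

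**Figure D1:**
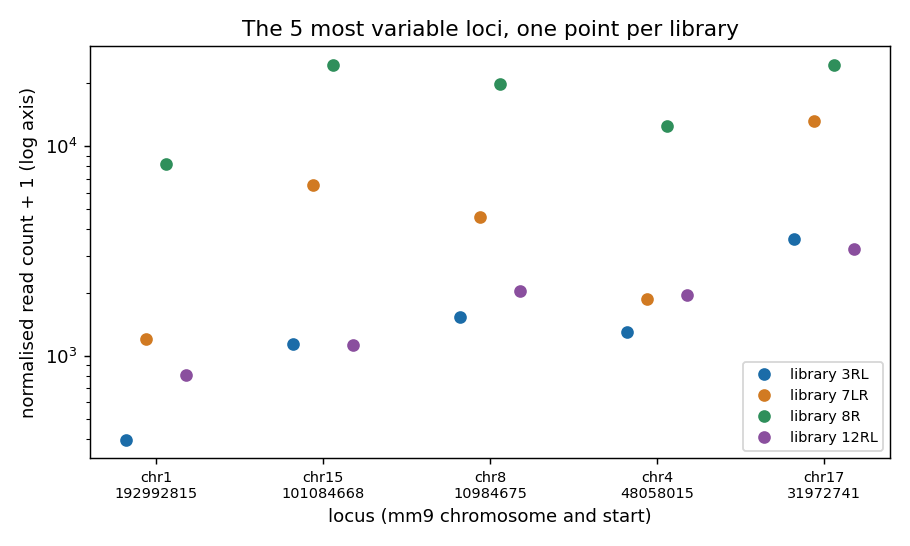
Normalised read count plus 1, on a log axis, of the 5 most variable loci, with 1 point per sham library and mm9 positions on the x axis. Library 8R is the highest point at each, with 8258 at the chr1 locus and 24356 at the chr15 locus.

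Over all 14424 loci, a library stood apart upward at 454 (3.15%) and downward at 209 (1.45%). Of the 15 most variable loci, 7 were among the 454. Simulated libraries without any effect, with 1 dispersion for all loci, gave 2.72% upward. The number of such loci was near that of these simulated libraries, so only their distribution over the libraries is compared. The interval below treats loci as independent, which they are not. Of the 454 upward loci, 214 were in 8R (47.1%, 95% Wilson interval 42.6 to 51.7), 133 in 3RL, 54 in 12RL and 53 in 7LR, where equal libraries would give 25.0% each and the simulated libraries had a highest share of 27.9%. Dixon's ratio was taken on untransformed values, and on log2 values the share of 8R was 47.9%. The share depended on the scaling and on transcript length. It was 41.9% with TMM scaling, 41.0% with the median of ratios over these 4 libraries and 17.6% with scaling to equal table totals, which ends the excess. Among loci with a UCSC model, it moved from 49.0% to 29.4% (95% interval 25.0 to 34.2) when the trend with spliced length was removed.

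Long and short transcripts deviated in opposite directions in these libraries. In 7LR and 12RL, loci whose longest spliced UCSC model exceeded 8 kb lay above the mean of the 4 libraries, with median log2 deviations of 0.15 and 0.15 over 368 loci. In 8R and 3RL the same loci lay below it, at -0.18 and -0.11. Models of up to 1 kb did the reverse, with medians of 0.19 in 8R, 0.04 in 3RL, -0.14 in 7LR and -0.09 in 12RL over 885 loci. Spearman's rho between the deviation and the spliced length, across 13251 loci, was -0.460 in 8R, -0.183 in 3RL, 0.311 in 12RL and 0.405 in 7LR. Deviations from a shared mean cannot all have the same sign, and loci are not independent replicates, so no p is given.

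**Figure D2:**
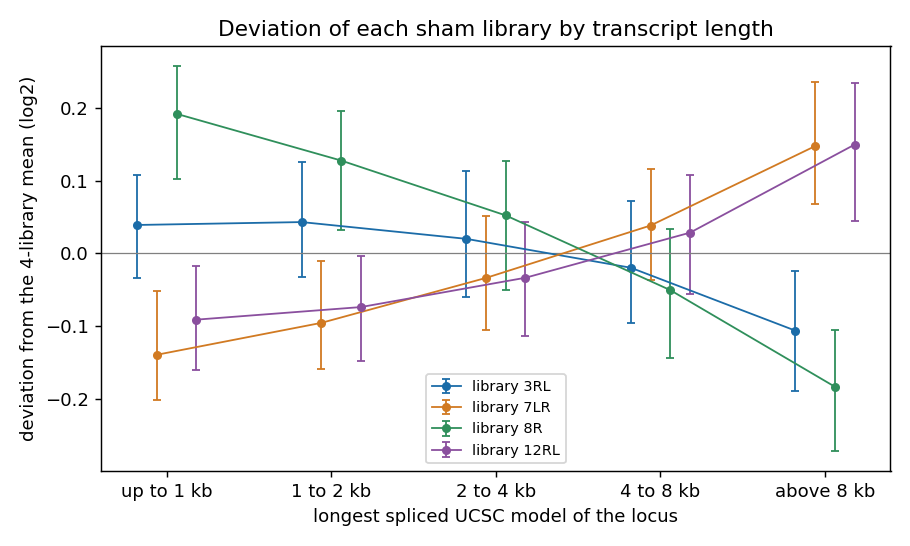
Median log2 deviation of each sham library from the mean of the 4 libraries (y axis) in 5 ranges of the longest spliced UCSC model (x axis); bars span the quartiles of the loci. Above 8 kb the medians are 0.15 in 7LR and -0.18 in 8R, and up to 1 kb they are -0.14 and 0.19.

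Loci without a UCSC model were numerous and had low counts. They made up 9221 of the 35299 loci, of which 8534 were intergenic, 8844 were above 0 in at least 1 library and 3958 had a mean of 10 or more. Together they took 0.591% ± 0.113 of the counts (SD, n = 4). Among loci with a mean above 0, their median log2 value lay below that of loci with a UCSC model in 4 of 4 libraries, by a mean of -6.45 ± 0.24 (exact two-sided sign-flip test, p = 0.125, the smallest that 4 libraries allow). This leaves out 7330 loci with a UCSC model and 377 without one that were at 0 in every library. With them included, the difference was -2.77, and restricted to loci with more than 1 exon it was -4.97. None of these differences was corrected for length.

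Loci without a UCSC model also varied more between libraries than loci with one matched on 10 bins of the mean. The median SD of log2 values was 0.44 for the 3958 loci, against 0.37 in matched sets (permutation p = 0.0002, two-sided, the smallest that 10000 sets can give). That p is across loci and not across animals. Counting error was not taken out, and means may still differ within a bin. At a minimum mean of 50 the medians were 0.30 against 0.25, with the same p. Loci without a UCSC model came from assembly of reads, while UCSC models are listed with or without reads. A locus high in 1 library may be assembled more easily, which may shape both the spread and the level. The difference of 0.07 fell to 0.03 for loci with more than 1 exon and to 0.04 with a pseudocount of 10, both with the same p. The most abundant spliced intergenic locus, at chr13 32792694 to 32872582 with up to 14 exons, had 68727 ± 15763 normalised counts (SD, n = 4). Next were the loci at chr10 56687348 to 56702278 with 10578 ± 1314, chr12 109441803 to 109513640 with 7370 ± 547, chr2 77148164 to 77155416 with 6460 ± 1276 and chr14 51508258 to 51517386 with 6214 ± 627.

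The assembled intergenic transcripts were simpler than the UCSC models. The file held 77650 transcript models, of which 49347 were UCSC models and 11433 were intergenic. Intergenic models had a median of 1 exon against 6 exons (permutation test across transcripts, p = 1e-05, the smallest that 100000 resamples can give), and 70.4% of them had a single exon, against 12.7% of UCSC models. Their median spliced length was 1419 bases against 2082 bases (p = 1e-05, permutation test). Among multi-exon models of 200 bases or more the order of length turned: intergenic models had a median of 2498 bases and UCSC models 2307, while the median number of exons stayed lower at 3 against 7.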

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

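The tests of explanations in this part were written after the patterns had been seen and before the tests were run, except that the median of ratios and the bound from simulated libraries were added after the results were seen. A few loci, 3 in number, were picked out because a single library lay far from the other 3, a criterion that chance alone meets in about 1 of 20 groups. At chr1 192992815 library 8R had 8258 normalised counts, with the next library at 1195. At chr8 10984675 library 8R had 19723, with the next at 4571. At chr4 48058015 library 8R had 12477, with the next at 1949. All 3 are among the most variable loci, so they were ranked on the same values.

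The deviations of each library followed transcript length, most strongly in 8R with a rho of -0.460. Explanations were tested in 8R only. There the trend was also present without the highest 10% by mean, with a rho of -0.443. Each locus counts once in a rank correlation, so leaving out so few loci could hardly have removed the trend. In 8R it was not carried by a difference in level between short and long models, since the mean rho within 10 bins of the mean was -0.514. Genomic span did not account for it in 8R, since the partial rho with spliced length given span was -0.358. In 3RL the deviations had a rho of -0.227 with the mean level and -0.193 with span, against -0.183 with spliced length. Level and span are therefore not set aside for 3RL. Length-dependent recovery of RNA or reads in library preparation may remain as an explanation, which no value tested here can separate from a difference between the hearts, and with 1 group no biological explanation was tested.

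Library 8R held 47.1% of the loci that stood apart upward, whose number was near that of simulated libraries without an effect, and 49.1% with every library thinned to the smallest depth, which argues against depth. Among loci with a UCSC model, removing the trend with spliced length moved the share from 49.0% to 29.4% (95% interval 25.0 to 34.2), so the trend may account for much or all of the excess. Removing the trend also re-centred each library, so it does not separate the trend from the scaling. The lower end, 25.02%, is just above an equal share, but an equal share is too low a bound, because 8R was picked as the highest library. The highest share in simulated libraries, 27.9%, lies within the interval of 25.0 to 34.2. Those libraries held loci of all kinds, with no trend removed and 1 dispersion for all loci, so they are a rough bound. Whether a remainder exists cannot be told. TMM scaling gave 41.9% (95% interval 37.3 to 46.7) and the median of ratios 41.0%. They changed the values of 8R by only -1.90% and -1.72%, so they test the authors' scaling little. Scaling to equal table totals, under which every locus of 8R fell by 6.44%, gave 17.6%. Abundant loci weigh most in such totals, and the 15 highest took 40.7% of the counts in 8R, the most of any library. Equal totals may thus lower 8R too far, and the scaling stays open as a cause. No biological explanation was tested, because the design has 1 group.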

How the results depend on the processing

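The comparisons of loci with and without a UCSC model, the trend with length, the share of loci standing apart and the neighbourhood test, with their alternatives, were chosen after seeing the data. So were 2 alternatives for the most variable loci that ran on loci with a UCSC model only, which 13 of the 15 have: 13 remained with that filter alone, as many as could, and 12 with the trend with length removed. The other alternatives were fixed before the data were examined. The greater spread of loci without a UCSC model and the odds ratio near abundant loci kept their direction and side of the threshold in all alternatives run, while the difference in spread ranged from 0.03 (multi-exon loci) to 0.08. The number of loci detected was 25692 at a mean of 1 and 14424 at a mean of 50, against 18912 at 10. The 15 highest loci took 16.5% of counts without mitochondrial loci. Of the 15 most variable loci, 6 remained with the SD of log2, 8 with edgeR's tagwise dispersion and 0 with the chi-square against Poisson, which ranks abundant loci first. Leaving out 1 library kept 7 (without 8R) to 13. The level difference of loci without a UCSC model was -5.51 with a pseudocount of 10, -6.07 at a mean of 10 or more, -4.97 for multi-exon loci and -2.77 with loci at 0 included, more of which have a UCSC model. The lowest Pearson r was 0.991 with a pseudocount of 10 and 0.983 with no minimum. The share of 8R among loci standing apart upward was 41.1% at a minimum mean of 10, 41.9% with TMM, 41.0% with the median of ratios and 17.6% with equal table totals. The rho with length in 8R was -0.391 at a minimum mean of 10, -0.525 at 200 and -0.386 for loci with 1 UCSC model, and -0.501 to -0.393 when another library was left out. The difference of median length turned to -191 bases for multi-exon models of 200 bases or more. Where no cause is stated, the cause was not tested. Not run, because loci have no gene symbols here or libraries no replicate numbers, were the alternatives for gene lists, gene pairs, coding against noncoding genes, replicate 4 and heart genes. No paired analysis was possible because there is 1 group. Depth limits loci near 10 reads, where counting error gives a CV of 31.6%.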

Other observations

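All tests in this part were chosen after the data had been seen. Chromosome Y was transcribed in each of the 4 hearts at a similar level. Its 4 loci with a mean of 10 or more were led by chrY 597215 to 623056 with 12498 ± 1092 normalised counts (SD, n = 4) and chrY 347055 to 386694 with 8392 ± 895. The other 2 were chrY 421634 to 582199 with 3565 ± 231 and chrY 234231 to 293224 with 2750 ± 248. Chromosome X took 1.25% ± 0.0333 of the counts.

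Spliced intergenic loci lay more often beside abundant loci. Of 1496 loci with a UCSC model in the highest 10% by mean, 201 (13.4%) had such a locus within 50 kb, against 1235 of 13458 other loci (9.18%; odds ratio 1.54, Fisher's exact test across loci, two-sided, p = 4.19e-07). Locus length, the density of loci and read-through from the abundant locus were not tested.

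The most abundant locus without a UCSC model had a single exon, at chr17 39979941 to 39985776. It alone took 0.171% ± 0.0852 of the counts (SD, n = 4), where all loci without a UCSC model took 0.591%. It had 436475 normalised counts in 3RL and 388625 in 12RL, against 177901 in 7LR and 161196 in 8R. The third of these single-exon loci, at chr6 3150767 to 3151670, had 27100 and 26677 against 12284 and 11066 in the same libraries. The others among the first 5 were highest in 12RL: chr3 5860333 to 5860778 with 110263 against 32950 to 48397, chr18 68851558 to 68851973 with 15743 against 7429 to 13582, and chr17 71313007 to 71313236 with 12405 against 6457 to 8007. What these single-exon loci are was not examined, so their counts are not shown to come from unannotated poly(A) transcripts.

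Some variable loci were low or at 0 in part of the libraries. The locus at chr14 26707889 to 27002074 had 752 normalised counts in 7LR and 690 in 8R, against 8.36 in 3RL and 1.58 in 12RL. A 2-exon locus without a UCSC model, not classed as intergenic, lay at chr12 24101595 to 24285273. It had 437 normalised counts in 7LR and 0 reads in the other 3 libraries, which allows up to 3 reads in each.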
